A study of Mus musculus with 12 samples.

How the data were processed

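RNA was sequenced from 12 samples of mouse spermatogonia, the dividing germ cells at the base of the seminiferous tubule, taken from testes of a C57BL6/129 background. Per the labels, each library was made from 1000 cells collected by fluorescence-activated sorting and amplified with Smart-seq2, a full-length cDNA method for small cell numbers. The samples form 4 groups of 3 libraries, WT and Tet1KO at 3 and at 11 months of age. The labels do not say that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

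The authors deposited a table of raw counts, 1 whole number per gene and library, for 53715 genes. Per the file headers, fragments were counted with featureCounts 1.6.2 on the GENCODE vM17 annotation, with a mapping quality minimum of 30, without strand, and with fragments that overlap several genes counted for each of them. Per the submitters' processing notes, HISAT2 and SAMtools were also used and the genome build was mm10. Their versions are not given in the sources used here. Without strand, reads of a gene and of an overlapping or antisense gene cannot be told apart. Gene symbols came from a GENCODE vM21 table matched on the gene identifier without its version, which gave a symbol for 53620 of the 53715 genes. Coordinates are those of the deposited table, in mm10.

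Total counts per library ran from 8325159 to 18223645. A count of 0 in a library allows up to 3 counts, which is 0.16 to 0.36 CPM (counts scaled to a common library total) at these depths, and this limit covers counting error only, since the reads carry no molecular identifiers. Pairs of libraries within a group differed by far more than counting noise alone, with a chi-square per degree of freedom of at least 10.9. Repeat libraries known to be of the same cells were not available to compare, so this does not show separate animals. Every library was counted as 1 replicate.

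Genes were tested from the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were removed with filterByExpr, which left 19815, and libraries were scaled with TMM. All 12 libraries entered a single model with 1 mean per group, and each comparison was a contrast of that model, tested with the robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment at 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Of 29 lists fixed before the data were examined, 27 had at least 5 tested members, and the Leydig cell list (3 tested members) and the erythroid list (1) were not tested. Beside the preset correlation, camera was run with a correlation estimated from the data, and fry was run as a rotation test. Median log2 fold changes of lists are over their members in the edgeR fit, and medians given for fits that leave out a library or use blocks are over the members' differences in log2 CPM in the camera fit, with the value for all libraries on that scale beside them. For single values, exact permutation tests were used.

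Genes named in the text were chosen by a rule fixed before the data were examined. It takes Tet1, Tet2 and Tet3, the germ cell stage genes Gfra1, Zbtb16, Kit, Stra8, Sycp3, Ddx4, Dazl and Prm1 and the Sertoli gene Sox9. It also takes the 6 highest and the 6 lowest fold changes past the threshold and up to 3 members of each fixed list past it. Where a comparison has no call, it takes the 5 genes with the smallest unadjusted p, given as not past the threshold, and this was so in all 6 comparisons. The other list members named as examples, the genes called by DESeq2 alone and the neutrophil genes were chosen after their values were seen.

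The edgeR procedure was tested on simulated counts with the means, dispersions and library sizes of these data. For Tet1KO against WT at 3 months, with 200 changed genes of an average log2 CPM of at least 3, it called 14 genes (7.00%) at a 2-fold change, 162 (81.0%) at 4-fold and 189 (94.5%) at 8-fold. The simulation did not include differences between libraries that many genes share, which the real libraries had. These shares therefore may not hold for the real data. A lack of calls there is no evidence against changes of 4-fold or 8-fold.

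Alternatives fixed before the data were examined were other scaling factors, other filters, mitochondrially encoded and ribosomal protein genes left out, DESeq2 1.42.0, limma-voom with sample quality weights, only the compared groups in the fit, the replicate number as a block, a threshold of 0.01 and each library left out in turn. Alternatives chosen after seeing the data left out WT replicate 1 and Tet1KO replicate 2 of 3 months together, used the spermatid list mean or the prefix of the library code as a covariate, kept only the 4 libraries of 3 months with 1 code prefix, used as blocks for genes and lists the pairs of 1 WT and 1 Tet1KO library that follow each other in the order of their codes (numbers 1 apart in 4 of the 6 pairs, and 3 and 19 apart in 2 pairs of 3 months), or fitted the 11-month libraries alone with the replicate block. Same-numbered WT and Tet1KO libraries deviated together from their group means at 11 months, with correlations of 0.37, 0.17 and 0.33 across genes, so the numbers were taken to pair these samples. At 3 months the correlations were -0.59, -0.18 and 0.30, and the numbers were not taken to pair them. The pairing comes from the values and not from the labels.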

Results

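Transcript levels were compared in sorted spermatogonia of WT and Tet1KO mice at 3 and 11 months of age, with 3 libraries per group. TET1 is an enzyme that oxidises 5-methylcytosine in DNA, and the series asks how its loss changes spermatogonial expression in younger and older animals. Total counts ran from 8325159 to 13622729 per WT library and from 9623251 to 18223645 per Tet1KO library at 3 months, and from 9572429 to 16248463 and from 8599667 to 16323020 at 11 months. Germ cell genes were abundant in every group. Dazl, an RNA-binding protein gene of germ cells, stood at 2180 ± 287 CPM (SD, n = 3) in WT and 2120 ± 345 CPM in Tet1KO at 3 months, and at 1930 ± 111 and 1980 ± 313 CPM at 11 months. Ddx4, a germ cell RNA helicase gene, stood at 325 ± 13.5, 345 ± 40.5, 300 ± 44.7 and 294 ± 9.35 CPM in the same order. Kit, the receptor gene of differentiating spermatogonia, lay between 84.9 ± 20.9 and 97.4 ± 17.7 CPM in the 4 groups.

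Libraries of a group differed widely. The first principal component held 39.0% of the variance and set WT replicate 1 (score -131) and Tet1KO replicate 2 (-121) of 3 months apart from the other 10 libraries. These had 29420 and 30010 genes with a count, against at most 26995 in the other 10. The second component, with 12.3%, set replicate 1 of both genotypes at 11 months (-64.2 and -70.5) apart from replicate 3 of both (43.1 and 53.1). Neither component separated the genotypes.

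**Figure D1:**
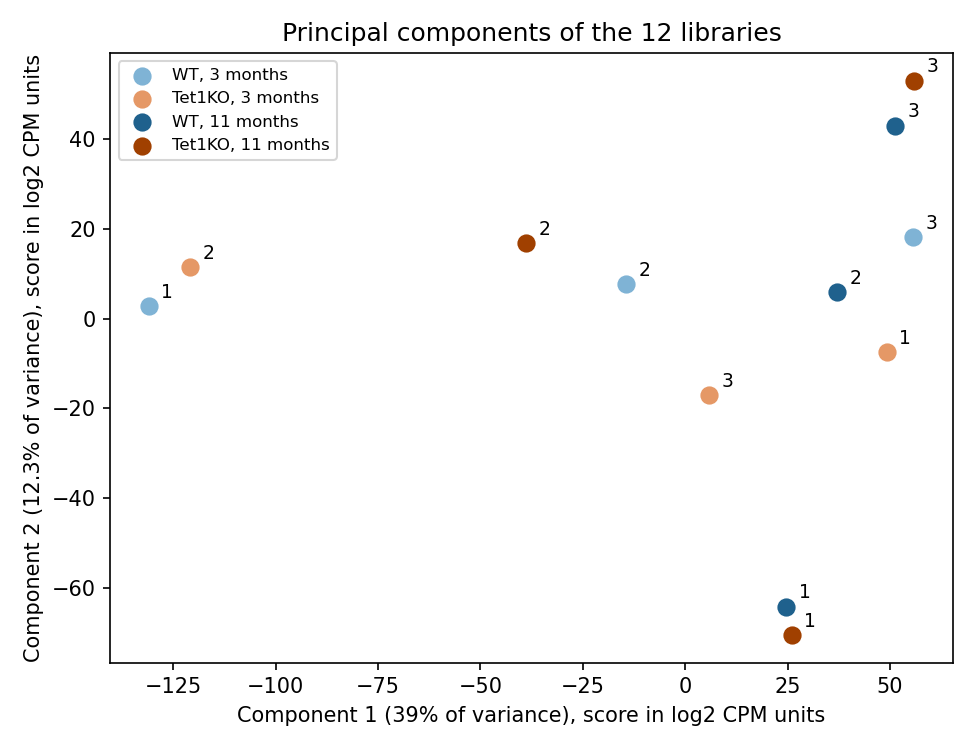
Scores of the 12 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, coloured by group and numbered by replicate. WT replicate 1 and Tet1KO replicate 2 of 3 months lie at -131 and -121 on the first component, away from the other 10 libraries.

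Tet1 itself (chromosome 10, 62804570 to 62908996, minus strand, mm10) was close to the detection limit and did not separate the labels. Its counts were 15, 16 and 0 in WT and 6, 11 and 18 in Tet1KO at 3 months, and 1, 16 and 5 in WT and 1, 17 and 5 in Tet1KO at 11 months. Mean levels were 0.925 ± 0.840 CPM (SD, n = 3) in WT and 0.981 ± 0.649 CPM in Tet1KO at 3 months, with an exact two-sided permutation p of 0.9. At 11 months they were 0.515 ± 0.436 and 0.729 ± 0.866 CPM, again with an exact permutation p of 0.9, where the smallest p that 3 against 3 libraries allow is 0.1. The labels do not say which exons the knockout allele lacks, and counts over the whole gene therefore do not check the genotype; WT and Tet1KO are used as the names of the labels. Tet3 was the most abundant family member, at 27.6 ± 3.44 and 28.3 ± 5.65 CPM in WT and Tet1KO at 3 months. Tet2 stood at 1.88 ± 0.694 and 3.38 ± 1.48 CPM, a log2 fold change of 0.84 ± 0.49 (SE) that did not pass the edgeR test; Tet2 overlaps Gm42567 on the opposite strand.

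**Figure D2:**
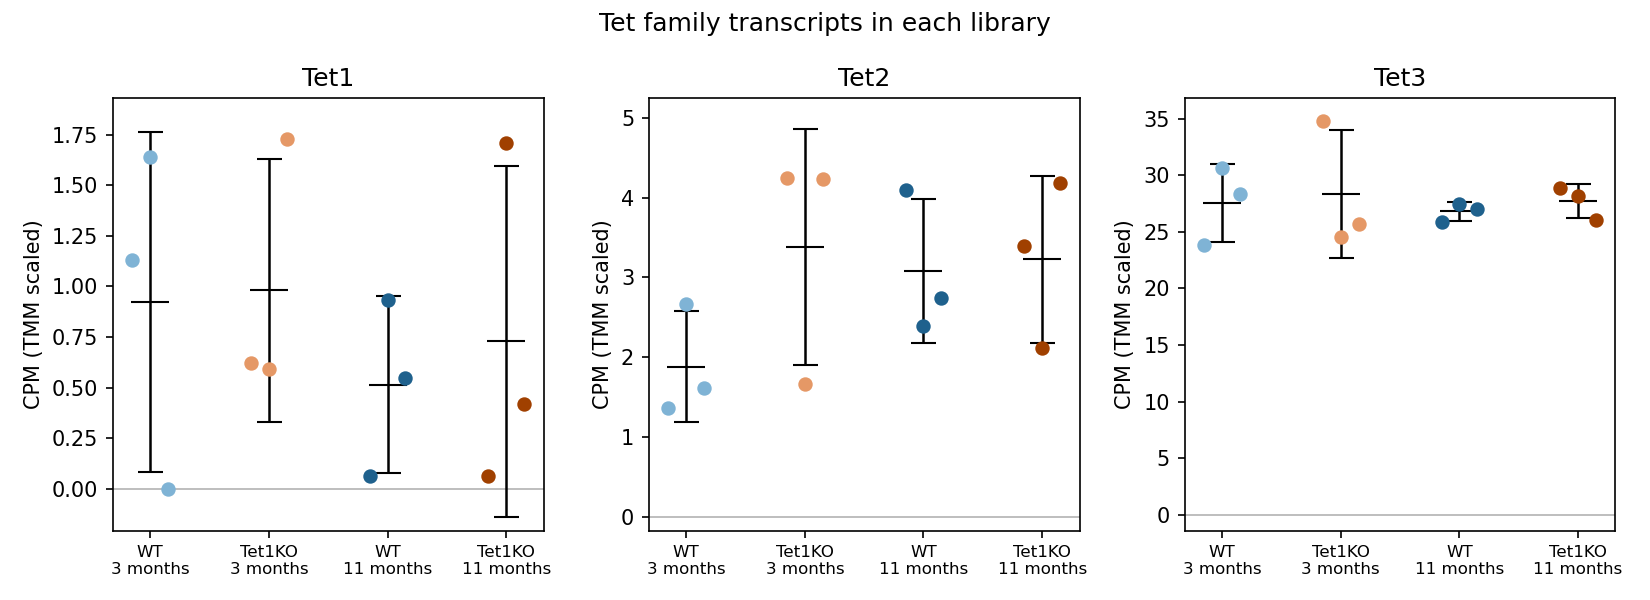
CPM of Tet1, Tet2 and Tet3 (y axis) in each library by group (x axis), with the mean and SD of the 3 libraries as bars. Tet1 lies near 0 in both genotypes, from 0 to 18 counts per library.

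At 3 months, Sertoli cell genes, which mark the somatic nurse cells of the tubule, were lower in Tet1KO than in WT libraries. These libraries cannot tell RNA of other cells in the sort from a change within spermatogonia. That limit also holds for the spermatid, peritubular myoid, leukocyte and stroma lists in all comparisons below. All 17 tested Sertoli members had lower values, with a median log2 fold change of -1.5. Aard stood at 6.73 ± 4.45 CPM (SD, n = 3) in Tet1KO against 19.5 ± 3.49 CPM in WT, a log2 fold change of -1.52 ± 0.49 (SE), and Cst12 at 12.3 ± 8.33 against 57.8 ± 39.8 CPM, neither past the threshold. The list mean was 4.08 log2 CPM in WT replicate 1, which stood apart on the first component, 2.84 and 2.58 in the other WT libraries, and 1.66, 2.70 and 1.38 in Tet1KO. Between WT and Tet1KO libraries paired by the order of their codes, whose numbers lie 3, 1 and 19 apart, the Tet1KO minus WT difference was -1.38, -1.19 and -1.19 log2 CPM, with WT replicates 1, 3 and 2 in that order. That pairing was chosen after seeing the data. Unpaired, the groups overlapped, with Tet1KO replicate 2 (2.70) above WT replicate 3 (2.58). Ribosomal protein genes were lower in 74 of 80 members (median -0.33), but by a median of -0.046 log2 CPM without WT replicate 3, against -0.29 with all libraries on that scale. Undifferentiated spermatogonia genes were higher in 19 of 29 members (median 0.27), among them Gfra1, the GDNF receptor gene of stem spermatogonia, at 34.3 ± 8.84 against 21.8 ± 7.17 CPM (log2 fold change 0.65 ± 0.36). Gfra1 overlaps Gm16277 on the opposite strand, and unstranded reads cannot tell them apart. The list median of 0.26 log2 CPM was 0.057 without WT replicate 3 and 0.036 without Tet1KO replicate 1. In the same pairs and order, the list means differed by -0.0165, -0.64 and -0.11 for ribosomal protein, 0.36, 0.24 and 0.16 for undifferentiated spermatogonia, -0.38, -0.38 and 0.034 for mitochondrially encoded, -0.13, -0.47 and 0.057 for oxidative phosphorylation, -0.38, -0.12 and -0.74 for senescence and -0.57, 0.36 and -0.92 for leukocyte genes. The meiotic genes Stra8 (-0.13 ± 0.52) and Sycp3 (-0.26 ± 0.45), and Zbtb16 (0.30 ± 0.48), Kit (0.20 ± 0.23), Prm1 (-0.79 ± 0.92) and Sox9 (-1.58 ± 1.14) did not pass the test. Sycp3 overlaps Chpt1 on the opposite strand.

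No gene passed the threshold at 3 months in edgeR's quasi-likelihood test of 19815 genes (0 genes), with 225 genes (1.14%) at an unadjusted p under 0.05. Evenly spread p values would give 991, but other splits of the same libraries gave a median of 508 and at most 3330. Without 1 library the real number ran from 159 to 512, with 353 without WT replicate 1 and 512 without Tet1KO replicate 2. DESeq2 called 2 genes, S100a8 and S100a9, which had 192 and 87 counts in Tet1KO replicate 3 and 0 in the other 5 libraries of that age, and limma-voom called 0. The smallest unadjusted p values in edgeR belonged to Gm15020, Prn, Gm6207, Hist3h2ba and Myl3, none past the threshold. Gm15020 and Gm6207 overlap each other on the X chromosome, Prn overlaps Prnp and Prnd, and Myl3 overlaps Pth1r on the opposite strand, so these 4 are uncertain. Gm15020 stood at 16, 4.10 and 41.9 CPM in the WT libraries and at 2.75 to 4.04 CPM in Tet1KO. Camera called 7 of 27 lists at its preset correlation, and 0 lists had members past the threshold adjusted over the list alone. The calls were Sertoli cell (adjusted p = 1.85e-08), ribosomal protein (4.85e-08), mitochondrially encoded (0.00132), nuclear encoded oxidative phosphorylation (0.00132), senescence and inflammatory secretion (0.00776), undifferentiated spermatogonia (0.0378) and leukocyte and macrophage genes (0.0480). All 7 were lost when the correlation was estimated, with adjusted p = 0.89 with an estimated correlation for each, and fry called 0 lists. Only the Sertoli call held without each library in turn, with a median difference on camera's log2 CPM scale of -1.1, and -1.8 without WT replicate 3. On the same scale the ribosomal protein median was -0.29 with all libraries and -0.046 without WT replicate 3, where the call ended (adjusted p = 0.89). The oxidative phosphorylation median of -0.23 turned to 0.00052 without WT replicate 3 (0.64) and was -0.20 without Tet1KO replicate 2 (0.17), and the mitochondrial median of -0.25 was -0.16 (0.11) and -0.23 (0.17) without the same 2 libraries, all of which ended these calls. The undifferentiated spermatogonia call, with a median of 0.26, ended without WT replicate 1 (median 0.30, adjusted p = 0.25), WT replicate 3 (0.057, 0.55), Tet1KO replicate 1 (0.036, 0.77) or Tet1KO replicate 2 (0.20, 0.17). It held at 0.44 without Tet1KO replicate 3. The leukocyte call, with a median of -0.36, ended without WT replicate 1 (median -0.16, adjusted p = 0.25), WT replicate 2 (-0.079, 0.31), Tet1KO replicate 1 (-0.16, 0.44) or Tet1KO replicate 2 (-0.37, 0.19). The senescence call, with a median of -0.35, ended without WT replicate 1 (median -0.20, adjusted p = 0.054), WT replicate 2 (-0.46, 0.087) or Tet1KO replicate 2 (-0.38, 0.093). It held at -0.53 without Tet1KO replicate 3. With these pairs as blocks, a pairing chosen after seeing the data that the labels do not state and in which only 1 pair of this age has adjacent code numbers, the medians stayed the same, the Sertoli call held (adjusted p = 5e-08) and the leukocyte (0.17) and senescence (0.10) calls ended.

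At 11 months, peritubular myoid genes, of the contractile cells around the tubule, were lower in Tet1KO libraries in 6 of 7 members, with a median log2 fold change of -2.0. Acta2, a smooth muscle actin gene, stood at 11.8 ± 10.4 CPM (SD, n = 3) in Tet1KO against 72.7 ± 38.4 CPM in WT, and Myl9 at 12.4 ± 7.05 against 48.6 ± 31.7 CPM. Leukocyte and macrophage genes were higher in all 17 members (median 0.74). The inducible heat shock genes Hspa1a and Hspa1b stood at 24 ± 11.6 and 13.3 ± 8.77 CPM in Tet1KO against 7.10 ± 2.40 and 3.78 ± 1.29 CPM in WT, and 20 of 22 immediate early and heat shock genes were higher (median 0.26). Proteasome genes were lower in 35 of 38 members, by a small median of -0.13, and Sertoli cell genes in 15 of 17 (median -1.1). Without WT replicate 2 the medians in log2 CPM went from 1.0 to 0.21 for leukocyte and from -0.46 to -0.027 for Sertoli cell genes. Between same-numbered libraries, 1 to 3 in order, the Tet1KO minus WT difference of the list mean was -2.48, -0.73 and -0.85 log2 CPM for peritubular myoid, -0.42, 3.28 and 0.46 for leukocyte, -0.28, 0.89 and 0.40 for heat shock, -0.078, -0.14 and -0.18 for proteasome, -0.80, -1.5 and 0.49 for Sertoli cell and -0.030, 1.29 and 0.45 for spermatid genes. Leukocyte, heat shock and Sertoli cell genes thus went the other way in 1 of the 3 pairs, and so did spermatid genes.

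No gene passed the threshold at 11 months in edgeR (0 genes), with 326 at an unadjusted p under 0.05, a number that ran from 323 to 714 without 1 library and was 714 without Tet1KO replicate 1. DESeq2 called 3 genes, with S100a8 and S100a9 counted in Tet1KO replicates 2 and 3 only and Tpm2, a tropomyosin gene, at a log2 fold change of -4.03 ± 0.88 (SE), and limma-voom called 0. The 5 smallest unadjusted p values belonged to B230312C02Rik (log2 fold change -1.82 ± 0.40, SE), Hspa1b (1.82 ± 0.45), Gm20481 (1.73 ± 0.43), Adamts1 (-2.45 ± 0.61) and Samd9l (3.81 ± 0.96), none past the threshold. Gm20481 (chromosome 17, 34969912 to 34972136) lies within Hspa1a (34969190 to 34972156) on the opposite strand, and unstranded reads count for both; Hspa1a and Hspa1b are near-identical copies. Germ cell stage genes did not pass the test, with Gfra1 at 0.52 ± 0.36, Zbtb16 at 0.61 ± 0.48 and Stra8 at -0.31 ± 0.52. Adjusted over the list alone, 4 of 7 peritubular myoid genes and 2 of 22 immediate early and heat shock genes passed, and no list member passed over all genes. Camera called 6 of 27 lists: leukocyte and macrophage (adjusted p = 1.75e-08), peritubular myoid (2.54e-06), immediate early and heat shock (7.02e-05), proteasome (0.000127), Sertoli cell (0.00564) and spermatid (0.0220). With an estimated correlation, in that order, the adjusted p = 0.55, 0.39, 0.61, 0.22, 0.83 and 0.97, and fry called 0 lists. On the log2 CPM scale the leukocyte median was 1.0 with all libraries, 1.6 without WT replicate 1 or WT replicate 3, and 0.21 without WT replicate 2, where the call ended (adjusted p = 0.25); the list mean of that library was 1.64 log2 CPM against 4.36 and 4.43 in the other WT libraries. The heat shock call, with a median of 0.25, ended without Tet1KO replicate 2 (median 0.069, adjusted p = 0.19). It held at 0.38 without WT replicate 1, 0.11 without WT replicate 2 and 0.45 without Tet1KO replicate 1. The Sertoli call, with a median of -0.46 on this scale, ended without WT replicate 1 (median -0.32, adjusted p = 0.10), WT replicate 2 (-0.027, 0.45) or Tet1KO replicate 3 (-0.55, 0.081). It held at -1.5 without WT replicate 3. The spermatid call, with a median of 0.56, ended without WT replicate 2 (median 0.54, adjusted p = 0.12), WT replicate 3 (0.073, 0.72), Tet1KO replicate 1 (0.23, 0.36) or Tet1KO replicate 2 (0.26, 0.43). It held at 0.98 without WT replicate 1 and 1.0 without Tet1KO replicate 3. The peritubular myoid and proteasome calls held without each library in turn.

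**Figure D3:**
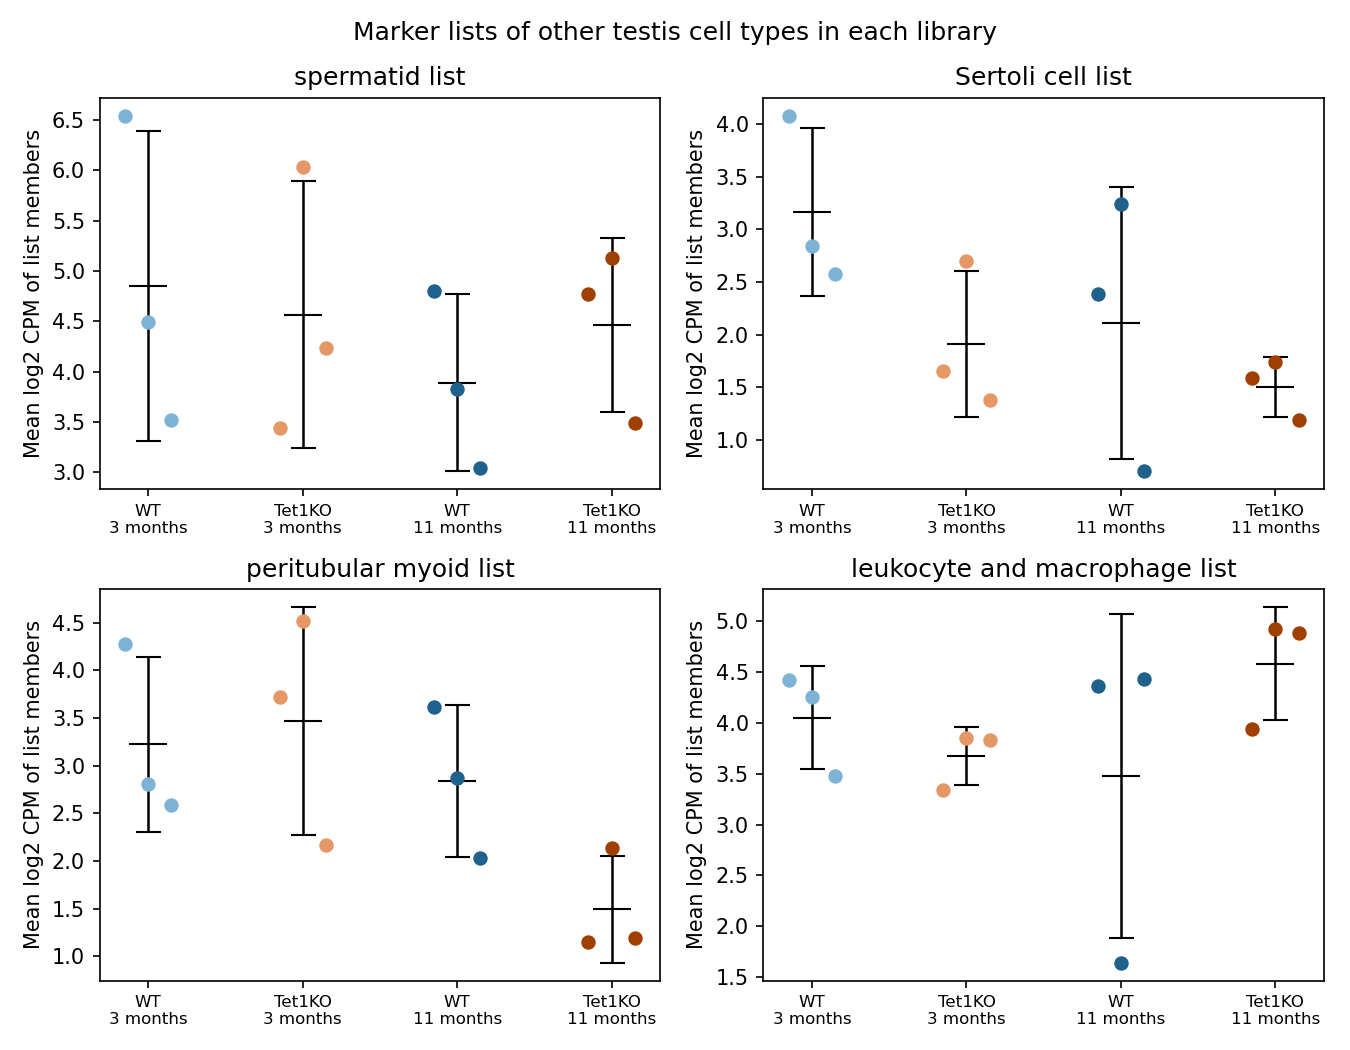
Mean log2 CPM of the spermatid, Sertoli cell, peritubular myoid and leukocyte and macrophage lists (y axes) in each library by group (x axis), with the mean and SD of the 3 libraries as bars. Peritubular myoid means at 11 months ran from 1.15 to 2.14 in Tet1KO and from 2.03 to 3.62 in WT, and spermatid means spread from 3.04 to 6.54 across libraries.

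Averaged over both ages, Sertoli cell genes were lower in Tet1KO in all 17 members (median log2 fold change -1.1). Cldn11, a tight junction gene of Sertoli cells, had a log2 fold change of -2.41 ± 0.83 (SE), Rhox5 of -1.66 ± 0.61 and Aard of -1.13 ± 0.35, none past the threshold. Gfra1, which overlaps Gm16277 on the opposite strand, was higher in Tet1KO by 0.59 ± 0.25 at an unadjusted p of 0.0395 in edgeR, and did not pass the threshold after adjustment. No gene passed (0 genes), with 283 at an unadjusted p under 0.05 (243 to 434 without 1 library, the highest without WT replicate 1 of 3 months); DESeq2 called 2 genes, S100a8 and S100a9, and limma-voom 0. The smallest p values belonged to Prn, Serpina3a, Gm44454, Mir22hg and Gm26732, none past the threshold. Serpina3a (log2 fold change -3.96 ± 1.01, SE) was low, at an average log2 CPM of -0.207. The others are uncertain, since Prn overlaps Prnp and Prnd, Gm44454 Hist1h2ak, Mir22hg Tlcd2 and Gm26732 Sidt1. Prn stood at 0.410 ± 0.0235 CPM (SD, n = 3) in Tet1KO, close to the detection limit, against 2.28 ± 1.05 CPM in WT at 3 months. Camera called 6 of 27 lists, of which the Sertoli call (adjusted p = 3.70e-10) held without each of the 12 libraries in turn, and 0 lists had members past the threshold adjusted over the list alone. The Sertoli call had an adjusted p = 0.65 with an estimated correlation. The others were ribosomal protein (0.00236), oxidative phosphorylation (0.00265), peritubular myoid (0.00475), leukocyte (0.0158) and heat shock genes (0.0239), each with an adjusted p = 0.89 with an estimated correlation. The ribosomal call, with a median of -0.11 log2 CPM, ended without WT replicate 3 of 3 months, where the median turned (0.00064, adjusted p = 0.91), Tet1KO replicate 2 of 3 months (-0.11, 0.087), or WT replicate 3 (-0.038, 0.47), Tet1KO replicate 1 (-0.064, 0.069) or Tet1KO replicate 2 (-0.0079, 0.99) of 11 months. It held at -0.19 without WT replicate 2 and -0.24 without Tet1KO replicate 3 of 11 months. The oxidative phosphorylation call, with a median of -0.10, ended without WT replicate 3 (median -0.0097, adjusted p = 0.95) or Tet1KO replicate 2 (-0.092, 0.099) of 3 months, or WT replicate 3 (-0.034, 0.33) or Tet1KO replicate 2 (0.011, 0.95) of 11 months. It held at -0.19 without WT replicate 2 and -0.22 without Tet1KO replicate 3 of 11 months. The leukocyte call, with a median of 0.34, ended without WT replicate 3 (median 0.24, adjusted p = 0.21), Tet1KO replicate 2 (0.29, 0.054) or Tet1KO replicate 3 (0.38, 0.12) of 3 months, or WT replicate 2 (-0.17, 0.34), Tet1KO replicate 2 (0.23, 0.19) or Tet1KO replicate 3 (0.32, 0.16) of 11 months. It held at 0.64 without WT replicate 1 and 0.59 without WT replicate 3 of 11 months. The heat shock call, with a median of 0.078, ended without WT replicate 3 (median 0.074, adjusted p = 0.21) or Tet1KO replicate 2 (0.035, 0.15) of 3 months, or WT replicate 2 (0.016, 0.30), Tet1KO replicate 2 (-0.0068, 0.86) or Tet1KO replicate 3 (0.096, 0.097) of 11 months. It held at 0.12 without Tet1KO replicate 3 of 3 months, and at 0.14 and 0.17 without WT replicate 1 and Tet1KO replicate 1 of 11 months. The peritubular myoid call, with a median of -0.49, ended without WT replicate 1 of 3 months (median -0.36, adjusted p = 0.12), Tet1KO replicate 3 of 3 months (-0.29, 0.13) or WT replicate 1 of 11 months (-0.29, 0.079). With libraries paired by code order as blocks the heat shock call ended (adjusted p = 0.058) and undifferentiated spermatogonia genes were called (0.047, against 0.081 without blocks, median 0.048).

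With age in WT, mitochondrially encoded genes were lower at 11 than at 3 months in all 13 members, with a median log2 fold change of -0.44. mt-Nd1, a subunit of respiratory complex I, stood at 10300 ± 2100 CPM (SD, n = 3) against 13800 ± 1390 CPM. Spermatid genes were lower in 23 of 24 members (median -0.69), Sertoli cell genes in 15 of 17 (median -1.0) and interstitial stroma genes in 10 of 12 (median -0.78). Proteasome genes were higher in 25 of 38 members (median 0.09) and proliferation genes in 25 of 35 (median 0.08). Rps4l, a ribosomal protein paralogue, stood at 172 ± 25.5 CPM against 114 ± 8.58 CPM, and Itgb8, an integrin subunit gene, had 0 counts in all 3 libraries of 11 months, which allows up to 0.31 CPM in the shallowest, against 1.83 ± 0.593 CPM at 3 months. The spermatid list mean was 6.54 log2 CPM in WT replicate 1 of 3 months, which stood apart on the first component, and 3.04 to 4.80 in the WT libraries of 11 months. Without that library the spermatid median turned to 0.15 log2 CPM. In both genotypes the ages also differ in their library codes. All 11-month libraries have higher code numbers than the 3-month libraries with the same prefix, and a second prefix occurs only at 3 months. Age therefore cannot be told apart from whatever the codes mark. The prefix was used as a covariate only for the genotypes at 3 months.

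No gene passed the threshold in edgeR (0 genes, smallest adjusted p = 0.774), with 1124 genes at an unadjusted p under 0.05, of which 470 were higher and 654 lower. Evenly spread p values would give 991, but other splits of the same libraries gave a median of 712 and at most 1481. DESeq2 and limma-voom also called 0 genes. The smallest p values belonged to Itgb8, Rps4l, 4930587E11Rik, Gm42798 and Fancd2os, none past the threshold; Rps4l resembles other ribosomal protein copies and Fancd2os overlaps Fancd2 on the opposite strand, so both are uncertain. Without 1 library, the number at an unadjusted p under 0.05 was 446, 1531 and 1607 without WT replicates 1, 2 and 3 of 3 months and 1277, 564 and 1048 without those of 11 months. Camera called 6 of 27 lists: mitochondrially encoded (adjusted p = 1.01e-05), Sertoli cell and interstitial stroma (both 0.00246), proteasome (0.00496), spermatid (0.00997) and proliferation (0.0265). With an estimated correlation the adjusted p = 0.66 for proteasome and 0.69 for the other 5, and 0 lists had members past the threshold adjusted over the list alone. The mitochondrial call held without each library in turn, with a median on the log2 CPM scale of -0.46, and -0.26 without WT replicate 2 of 11 months. The spermatid median of -0.69 turned to 0.15 without WT replicate 1 of 3 months (adjusted p = 0.86) and was -0.14 without WT replicate 3 of 11 months (0.45). The call held at -1.3 without WT replicate 3 of 3 months and -1.5 without WT replicate 1 of 11 months. The Sertoli call, with a median of -1.1, ended without WT replicate 1 of 3 months (median -0.66, adjusted p = 0.084) or WT replicate 3 of 11 months (-0.49, 0.30). It held at -1.8 without WT replicate 2 of 11 months. The stroma call, with a median of -1.1 on this scale, ended without WT replicate 2 (median -0.87, adjusted p = 0.082) or WT replicate 3 (-0.79, 0.12) of 11 months. It held at -1.9 without WT replicate 1 of that age. The proteasome call, with a median of 0.091, ended without WT replicate 1 of 3 months (median 0.058, adjusted p = 0.084) or WT replicate 3 of 11 months (0.035, 0.12). It held at 0.16 without WT replicate 3 of 3 months and 0.14 without WT replicate 1 of 11 months. The proliferation call, with a median of 0.084, ended without WT replicate 1 of 3 months (median 0.10, adjusted p = 0.36) or WT replicate 2 (0.043, 0.21) or 3 (0.063, 0.21) of 11 months. It held at 0.13 without WT replicate 2 or 3 of 3 months and 0.21 without WT replicate 1 of 11 months.

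With age in Tet1KO, peritubular myoid genes were lower at 11 months in all 7 members (median log2 fold change -2.6) and interstitial stroma genes in all 12 (median -1.3). Acta2 stood at 11.8 ± 10.4 CPM (SD, n = 3) against 118 ± 79.9 CPM, and Cald1, an actin-binding protein gene of smooth muscle, at 1.46 ± 0.793 against 9.54 ± 1.38 CPM. Slc38a5, a glutamine transporter gene, stood at 0.560 ± 0.101 against 9.62 ± 4.46 CPM. Hspa1a stood at 24 ± 11.6 against 5.19 ± 0.799 CPM and Hspa1b at 13.3 ± 8.77 against 3.00 ± 0.486 CPM. Leukocyte and macrophage genes were higher in all 17 members (median 0.85), immediate early and heat shock genes in 17 of 22 (median 0.44) and ribosomal protein genes in 76 of 80 (median 0.30). Without Tet1KO replicate 3 of 11 months the ribosomal median turned to -0.042 log2 CPM. Tet1KO replicate 2 of 3 months, which stood apart on the first component, had the highest peritubular myoid and stroma list means of its group. They were 4.52 log2 CPM against 3.72 and 2.17, and 4.06 against 3.09 and 3.35. Without it and WT replicate 1 of that age, the medians in log2 CPM were -1.9 for peritubular myoid and -1.3 for stroma genes, against -2.2 and -1.5 with all libraries.

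No gene passed the threshold in edgeR (0 genes), with 462 at an unadjusted p under 0.05. Without 1 library this number ran from 292 to 771, with 292 without Tet1KO replicate 2 of 3 months and 764 and 771 without Tet1KO replicates 1 and 2 of 11 months. DESeq2 called 7 genes, with Hspa1a, Hspa1b and Gm20481 higher and Myl9, Tpm2, Cald1 and Slc38a5 lower at 11 months, and limma-voom called 0. In edgeR the log2 fold changes were -4.07 ± 0.74 (SE) for Slc38a5, -2.72 ± 0.62 for Cald1, 2.20 ± 0.47 for Hspa1a, 2.15 ± 0.46 for Hspa1b and 2.08 ± 0.43 for Gm20481, none past the threshold. Adjusted over the list alone, 5 of 7 peritubular myoid genes and 3 of 22 immediate early and heat shock genes passed. Camera called 5 of 27 lists: peritubular myoid (adjusted p = 8.63e-09), ribosomal protein (3.34e-08), leukocyte and macrophage (1.08e-06), immediate early and heat shock (1.76e-06) and interstitial stroma (1.87e-05). With an estimated correlation, in that order, the adjusted p = 0.50, 0.94, 0.85, 0.68 and 0.68, and fry called 0 lists. The ribosomal protein call ended without Tet1KO replicate 3 of 11 months, where its median on the log2 CPM scale turned from 0.25 to -0.042 (adjusted p = 0.75), and held at 0.46 without Tet1KO replicate 2 of 11 months. The other 4 held without each library in turn. Without Tet1KO replicate 2 of 11 months the heat shock median went from 0.38 to 0.20 (adjusted p = 0.032) and the leukocyte median from 0.83 to 0.49, and without Tet1KO replicate 3 of 11 months the stroma median went from -1.5 to -0.94.

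The interaction compared the Tet1KO minus WT difference between the ages. Leukocyte and macrophage genes had a more positive difference at 11 than at 3 months in all 17 members (median log2 fold change 0.97), and peritubular myoid genes a more negative one in all 7 (median -2.2). Hspa1a (2.40 ± 0.64, SE) and Gm20481 (2.52 ± 0.60), which share reads, had among the smallest p values, with B230312C02Rik (-2.34 ± 0.56), Gm28417 (2.42 ± 0.66), which overlaps Ptpn18 on the opposite strand, and Myl3 (-3.08 ± 0.83), none past the threshold. No gene passed in edgeR (0 genes), with 311 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Without 1 library the number ran from 233 to 645, with 643 without Tet1KO replicate 2 of 3 months and 645 and 515 without Tet1KO replicates 1 and 2 of 11 months. Camera called 8 of 27 lists, and adjusted over the list alone 2 of 22 immediate early and heat shock genes passed. The leukocyte (adjusted p = 1.34e-07) and peritubular myoid (8.39e-05) calls held without each of the 12 libraries in turn, and both had an adjusted p = 0.86 with an estimated correlation. On the log2 CPM scale the leukocyte median was 1.5 with all libraries and 0.43 without WT replicate 2 of 11 months, whose list mean was 1.64 log2 CPM against 4.36 and 4.43 in the other WT libraries of that age. Between libraries paired by code order the leukocyte list mean differed by -0.42, 3.28 and 0.46 log2 CPM at 11 months and by -0.57, 0.36 and -0.92 at 3 months. The peritubular myoid median was -1.4 with all libraries, -2.5 without Tet1KO replicate 3 of 3 months, and -2.1 and -2.2 without WT replicate 3 and Tet1KO replicate 2 of 11 months. The other 6 had an adjusted p of 7.96e-05 for ribosomal protein, 0.00174 for proteasome, 0.00185 for heat shock, 0.00281 for mitochondrially encoded, 0.0219 for spermatid and 0.0239 for senescence genes. With an estimated correlation the adjusted p = 0.46 for proteasome and 0.88 for the other 5, and fry called 0 lists. The spermatid median of 0.60 log2 CPM turned to -0.17 without WT replicate 1 of 3 months, where the call ended (adjusted p = 0.87). The spermatid call also ended without Tet1KO replicate 1 (median 0.24, adjusted p = 0.48) or Tet1KO replicate 3 (0.48, 0.073) of 3 months, or WT replicate 2 (0.63, 0.071), WT replicate 3 (0.13, 0.64), Tet1KO replicate 1 (0.38, 0.22) or Tet1KO replicate 2 (0.51, 0.23) of 11 months. It held at 1.4 without WT replicate 3 or Tet1KO replicate 2 of 3 months and at 1.3 without WT replicate 1 or Tet1KO replicate 3 of 11 months. The ribosomal call, with a median of 0.36, ended without WT replicate 3 of 3 months (median 0.089, adjusted p = 0.69), or WT replicate 2 (0.18, 0.20) or Tet1KO replicate 3 (0.022, 0.94) of 11 months. It held at 0.55 without Tet1KO replicate 2 of 11 months. The mitochondrial call, with a median of 0.25, ended without WT replicate 3 (median 0.18, adjusted p = 0.068) or Tet1KO replicate 2 (0.23, 0.082) of 3 months, or WT replicate 2 (0.13, 0.20) or Tet1KO replicate 3 (0.083, 0.24) of 11 months. It held at 0.43 without WT replicate 1 and 0.48 without Tet1KO replicate 2 of 11 months. The senescence call, with a median of 0.53, ended without WT replicate 1 (median 0.64, adjusted p = 0.055), WT replicate 2 (0.55, 0.058) or Tet1KO replicate 2 (0.47, 0.074) of 3 months, or WT replicate 2 (0.12, 0.37) or Tet1KO replicate 2 (0.36, 0.23) of 11 months. It held at 0.84 without Tet1KO replicate 1 of 11 months. The heat shock call, with a median of 0.35, ended without Tet1KO replicate 2 of 11 months (median 0.20, adjusted p = 0.23). It held at 0.22 and 0.19 without Tet1KO replicates 1 and 3 of 3 months and 0.21 without WT replicate 2 of 11 months. The proteasome call, with a median of -0.16, ended without WT replicate 1 of 3 months (median -0.14, adjusted p = 0.055). With libraries paired by code order as blocks the senescence call ended (adjusted p = 0.16) and oxidative phosphorylation genes were called (0.017, against 0.20 without blocks, median 0.25).

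Of the 27 lists, 14 were called in none of the 6 comparisons. DNA methylation and demethylation genes (21 tested) had a smallest adjusted p of 0.343 over the comparisons, with medians from 0.01 to 0.08. Telomere maintenance genes (24 tested) had a smallest adjusted p of 0.21, homologous recombination and DNA damage repair genes (36) and imprinted genes (29) of 0.14, piRNA pathway genes (22) of 0.242 and meiotic prophase genes (44) of 0.205. The smallest adjusted p was 0.257 for differentiating spermatogonia, 0.451 for pan-germ cell, 0.317 for GDNF, FGF and retinoid signalling, 0.343 for p53 target, 0.205 for interferon response, 0.0998 for oxidative stress, 0.312 for endothelial and 0.0789 for X-linked Rhox cluster genes. The sign of the median differed from that of the mean or of the camera test for several lists that were not called, such as interstitial stroma over both ages (median -0.40, mean -0.28, camera direction up, adjusted p = 0.929).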

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

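The tests of later germ cells, of genotype and age for 2 libraries, of the order of library codes and replicate numbers and of S100a8 by genotype were chosen after the results were seen. The rules for depth and for neutrophil genes were written before those tests, but for patterns already seen in these data. The interaction of age and genotype passed camera's threshold at the preset correlation for 8 lists, which by that test had a different Tet1KO minus WT difference at the 2 ages. The adjusted p was 0.0219 for spermatid genes (median log2 fold change 0.72), 8.39e-05 for peritubular myoid (-2.2), 1.34e-07 for leukocyte and macrophage (0.97), 0.0239 for senescence and inflammatory secretion (0.50), 0.00185 for immediate early and heat shock (0.35), 7.96e-05 for ribosomal protein (0.43), 0.00281 for mitochondrially encoded (0.24) and 0.00174 for proteasome genes (-0.16). The spermatid median turned without WT replicate 1 of 3 months, from 0.60 to -0.17 on the log2 CPM scale (adjusted p = 0.87), and was 0.13 without WT replicate 3 of 11 months (0.64). Over all fits without 1 library the medians on that scale ran from -0.17 to 1.4 for spermatid, -2.5 to -1.1 for peritubular myoid, 0.43 to 2.1 for leukocyte and macrophage, 0.12 to 0.84 for senescence, 0.19 to 0.51 for heat shock, 0.022 to 0.55 for ribosomal protein, 0.083 to 0.48 for mitochondrially encoded and -0.22 to -0.13 for proteasome genes, and of the 8 calls only the peritubular myoid and leukocyte ones held in every such fit. With a correlation estimated from the data 0 of the 8 held, with a smallest adjusted p of 0.46 over all lists.

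WT replicate 1 and Tet1KO replicate 2 of 3 months stood apart from the other 10 libraries. Depth is argued against for their higher number of genes with a count. After thinning every library to 8325159 counts, the lower of the 2 still had 1129 more such genes than the highest of the others. The first component was not recomputed from thinned counts, so depth was not tested for the distance on it. Genotype as labelled does not by itself set the 2 libraries apart, since 1 is WT and 1 Tet1KO. Age does not either, since the other 4 libraries of 3 months did not lie with them. The nearest of these 4 lay 106 away on the first component, against an SD of 32.2 over the other 10. The 2 were picked by their scores on that component, so this distance restates the pattern and is no separate test. A wrong label was not tested and stays open. RNA of later germ cells in the sorted cells is a candidate explanation, since the mean of these 2 libraries was above the mean of the other 10 for all 24 spermatid genes, by a median of 1.85 log2 units, and both libraries were above each of the other 10 for 13 of them. Ldhc, a lactate dehydrogenase gene of meiotic and haploid germ cells, stood at 1550 and 1590 CPM in these 2 and at most 292 CPM in the others, while Prm1 stood at 747 and 275 CPM in these 2 and at 722 CPM in WT replicate 1 of 11 months. The excess was not confined to later germ cell genes. These 2 libraries also had the highest peritubular myoid list means, at 4.28 and 4.52 log2 CPM against at most 3.72. The Sertoli list mean was highest in WT replicate 1 (4.08) but not in Tet1KO replicate 2 (2.70). Leukocyte means of 4.42 and 3.85 were not the highest.

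WT and Tet1KO libraries paired by the order of their codes in the labels deviated together from their group means, with correlations of 0.71, 0.30 and 0.20 at 3 months, where the code numbers lie 3, 1 and 19 apart, and 0.37, 0.17 and 0.33 at 11 months, where they lie 1 apart. Of the 36 ways to match WT with Tet1KO libraries within each age, 2 gave a mean correlation as high, the code pairs themselves included. The code pairs gave 0.345, and a different matching at 3 months gave 0.346. The exact share was 0.0556, so shared preparation may link the code pairs but stays open. The replicate numbers of the labels, taken at both ages together, gave an exact share of 0.389, which leaves that explanation open as well. At 3 months alone the correlations by number were -0.59, -0.18 and 0.30, and the numbers were not taken to pair those samples. Shared litters or animals were not tested.

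S100a8 and S100a9, abundant in neutrophils, had counts in 3 of the 6 Tet1KO libraries (S100a8 192, 156 and 221) and in 0 of the 6 WT libraries. Of 20 other neutrophil markers, Retnlg, Ngp and Ly6g had 0 counts in every library. The summed CPM of the markers had a mean rank of 5.67 of 12 in the 3 libraries (exact one-sided permutation p = 0.7). The rule, written before this test but after the S100a8 pattern was seen, took a mean rank at or below the middle as against neutrophil RNA. This rank met it. It lies below the middle by less than the SD of 1.81 over all picks of 3, a margin that the rule did not ask for. Il1r2 and Padi4 were counted in all 12 libraries. In Tet1KO replicate 2 of 3 months, with 0 counts of S100a8, Il1r2 gave 230 of the 442 marker counts. The rule was met, but with this spread and with such markers in the sum it cannot decide on neutrophil RNA. The genotype could also be the source and stays open (Fisher's exact p = 0.182, two-sided).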

How the results depend on the processing

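Leaving out WT replicate 1 and Tet1KO replicate 2 of 3 months together, the covariates and the blocks by code order were chosen after seeing the data. The count of genes past the threshold was 0 in 121 of 125 results under alternative settings of edgeR, DESeq2 and limma-voom. The exceptions were DESeq2's 2 genes at 3 months, 3 at 11 months, 2 over both ages and 7 with age in Tet1KO, and the cause was not tested. In each of the 6 comparisons, 1 of these settings was the threshold of 0.01 on the unchanged main fit, where 0 was certain. The number at an unadjusted p under 0.05 ran from 120 to 1689, over filters that kept different numbers of genes. The lowest was at 3 months with a mean count of at least 50, and the highest with age in WT without a filter. With a replicate block the count was 0 in all 6 comparisons, also in the 11-month libraries alone (0 genes, 627 at an unadjusted p under 0.05), and of 38 list calls 36 held. At 3 months, where the numbers were not taken to pair the samples, the undifferentiated spermatogonia (adjusted p = 0.055) and leukocyte (0.091) calls ended. The block also called 3 lists that were not called without it, at unchanged medians: proteasome over both ages (0.041, against 0.060), and oxidative phosphorylation with age in Tet1KO (0.007, against 0.076) and for the interaction (0.018, against 0.20). The block was run for lists only at the preset correlation, and without it no list was called at an estimated correlation. Of 2080 values of named genes under alternatives, 165 (7.93%) had the other sign, and none of these genes passed the threshold in edgeR with all libraries. Values at the threshold of 0.01 came from the unchanged main fit and could not change sign. No scaling moved the median of all genes by over 0.1.

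The number of lists called fell to 0 in all 6 comparisons with an estimated correlation and with fry. Leaving out 1 library at a time, it ranged from 3 to 8 at 3 months (7 with all libraries), 6 to 10 at 11 months (6), 2 to 10 over both ages (6), 3 to 11 with age in WT (6), 5 to 9 with age in Tet1KO (5) and 5 to 12 for the interaction (8), and 11 of the 38 calls held in every such fit. Without the 2 libraries of 3 months that stand apart it was 3 at 3 months, 6 at 11 months, 6 over both ages, 1 with age in WT, 7 with age in Tet1KO and 5 for the interaction. With libraries paired by code order as blocks (adjacent numbers in 4 of the 6 pairs), 23 of 27 calls of the genotype comparisons and the interaction held and 2 lists were called that were not without them. Lists that were called with or without 1 library, and whose direction in camera or sign of the median turned without it, had these ranges of median difference in log2 CPM; fewer libraries were in the fit and the cause was not otherwise tested. Ribosomal protein genes ran from -0.24 to 0.00064 over both ages, -0.23 to 0.26 at 11 months, -0.28 to 0.14 with age in WT and -0.042 to 0.46 with age in Tet1KO. Oxidative phosphorylation genes ran from -0.33 to 0.00052 at 3 months, -0.24 to 0.26 at 11 months, -0.22 to 0.011 over both ages and -0.29 to 0.12 with age in WT. Spermatid genes ran from -1.5 to 0.15 with age in WT (0.15 also without the 2 libraries that stand apart), -0.45 to 0.60 with age in Tet1KO (0.60 without these 2) and -0.17 to 1.4 for the interaction. Immediate early and heat shock genes ran from -0.0068 to 0.17 over both ages, undifferentiated spermatogonia from -0.30 to 0.22 with age in Tet1KO and senescence from -0.16 to 0.14 at 11 months. Interstitial stroma ran from -0.67 to 0.71 at 11 months and -0.71 to 0.71 for the interaction, leukocyte from -0.17 to 0.64 over both ages, meiotic prophase from -0.19 to 0.16 at 11 months, -0.29 to 0.20 with age in Tet1KO and -0.12 to 0.21 for the interaction, and the Rhox cluster from -0.14 to 0.17 with age in Tet1KO. Tet1 in CPM of the plain total differed by 0.055 at 3 and 0.28 at 11 months, against 0.056 and 0.21 with TMM. Depth limits genes such as Tet1, with at most 18 counts per library.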

Other observations

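All tests of this part were chosen after the results were seen. Late germ cell transcripts varied between the libraries of every group. The spermatid list mean was 6.54, 4.49 and 3.52 log2 CPM in WT and 3.44, 6.03 and 4.23 in Tet1KO at 3 months, and 4.80, 3.83 and 3.04 in WT and 4.77, 5.13 and 3.49 in Tet1KO at 11 months. Prm2, a protamine gene of elongating spermatids, ranged from 82.2 to 841 CPM, and Acr, the acrosin gene, from 0.827 to 60 CPM. Dcn, a stromal proteoglycan gene, stood at 453 ± 137 CPM (SD, n = 3) in WT at 3 months and 238 ± 332 CPM in WT at 11 months.

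Other splits of the same libraries were compared with the real ones. With 10 splits of 3 against 3 libraries no share under 0.05 is possible; the real count was 0 genes in each of these 4 comparisons, and the highest other count was 0 at 3 months, 0 at 11 months, 1 with age in WT and 0 with age in Tet1KO. For the mean of both ages, all 100 splits drawn of 200 gave at least the real 0 genes and the highest other gave 652, and for the interaction all 100 did and the highest other gave 5. With a real count of 0 every split gives at least as many, so these counts decide nothing. At an unadjusted p under 0.05, the real split gave 283 genes over both ages, where 87 of the 100 splits gave as many (median of the others 788, highest 4382), and 311 for the interaction, where 86 did (815, 4083), so by this count chance cannot be excluded for either. These splits did not keep libraries paired by code order together. With those pairs as blocks the real counts were 589 over both ages and 903 for the interaction, and no splits within pairs were made to set beside them. The real splits of 3 against 3 gave 225 genes at 3 months (7 of 10 splits as many, median of the others 508, highest 3330), 326 at 11 months (9 of 10, 1211, 2053), 1124 with age in WT (4 of 10, 712, 1481) and 462 with age in Tet1KO (8 of 10, 901, 1775), where 10 splits are too few for a share under 0.05. The split with 652 genes put together WT replicates 1 and 2 and Tet1KO replicate 2 of 3 months with WT replicate 1 and Tet1KO replicates 1 and 2 of 11 months. These 6 have the highest spermatid list means (4.49 to 6.54 against 3.04 to 4.23), which points to a structure of the samples that may be late germ cell content rather than genotype. That list mean was used as a covariate only with the real genotype groups. There edgeR called 0 genes for the mean of both ages with and without it, with 373 and 283 genes at an unadjusted p under 0.05. The split with 652 genes was not refitted with the covariate, so this fit does not test what set that split apart.

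DNA of the 129 strain kept around a targeted gene could alter expression near Tet1. Of 398 tested genes within 20 Mb of Tet1, 4 (1.01%) had an unadjusted p under 0.05 in the mean of both ages, against 279 of 19416 other genes (1.44%), with a two-sided Fisher's exact p of 0.667. At 3 months the shares went the other way, with 8 of 398 (2.01%) against 217 of 19416 (1.12%) and a p of 0.0951, so these counts leave the question open.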
